A study of Mus musculus with 11 samples.

How the data were processed

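RNA of 11 libraries was compared, each made from Kit+ (CD117 bead-selected) bone marrow cells of C57BL/6 mice grown with FLT3, IL-6, IL-3 and stem cell factor, per the labels' protocols. The cells of the BCR/ABL libraries were transduced with BCR/ABL and a yellow fluorescent marker, sorted for the marker, and treated for 4 h where a drug is named. How the vector control was made is not given in the sources used here. Libraries were made with a stranded mRNA kit, per the labels' protocols. The unit of the labels' doses is in doubt and doses are not given here. Groups were taken from the labels: 1 vector control, 2 untreated BCR/ABL, 2 imatinib, 2 DFC+BCI, 2 imatinib+DFC+BCI, 1 untreated BCR/ABL library labelled as deleted for c-Fos and Dusp1, and 1 such library with imatinib. DFC and BCI were given together as the inhibitors of FOS and Dusp1. The labels describe the treated cells as duplicates and do not say whether duplicates came from different animals. If they did not, the p-values below describe repeated treatment and not animals.

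The authors aligned reads with TopHat to mm10 and estimated expression with Cufflinks, per the submitters' processing notes, which give no versions. The deposited values were taken as FPKM (fragments per kilobase of transcript, scaled to sequencing depth), because the file header names no unit and the values have the form that Cufflinks writes. The table has 23444 rows, of which 5019 are 0 in all 11 libraries. In 27 rows a spreadsheet had turned the symbol into a date, so those genes could not be named, and 2 rows share a symbol. Column totals were 459559 to 529427 FPKM. Read counts are not in the table, so the absolute depth is unknown and no interval from counts is given. An exact 0 can be a failed estimate, since Slc38a10 was listed at 0 in 3 libraries and at 28.0 to 35.4 FPKM in the other 8. Genes with near-identical copies (Hspa1a and Hspa1b, Eif3j1 and Eif3j2, the globins, Stfa, Ear, Bcl2a1, Csf2rb and histone genes) may have had reads divided between copies.

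Values were used as deposited, on the log2(FPKM + 1) scale, which understates changes of genes with low values. Genes with at least 1 FPKM in at least 2 libraries were kept, leaving 11442. The 6 comparisons between replicated groups were tested with limma 3.58.1 in R 4.3.3 (limma-trend, 2-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05). All 11 libraries entered 1 fit with 1 coefficient per group. The 4 groups with 2 libraries gave 4 residual degrees of freedom, and the fit added 3.2 prior degrees of freedom. The other 3 groups have 1 library, so comparisons with them have no replicate check and no p-value. For those, a gene was called higher or lower if it reached 5 FPKM in the higher group and differed by at least 1 on the log2 scale from each library of the other group. Every adjusted p for a gene below is from limma.

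Before the data were examined, 31 gene lists were fixed. The list of mitochondrially encoded genes had no measured member, and those of B lymphoid and of stromal and endothelial markers had fewer than 5, so 28 lists were tested. Tests used limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list change, and camera whether they change more than other genes. The estimated correlation rests on 4 residual degrees of freedom, and 0 lists passed that version in the 6 comparisons. Its power was not tried on simulated data, so a list that fails it is neither supported nor contradicted by that failure. For lone libraries, the median of a list was placed among 10000 random lists of the same size and similar mean expression. Some lists share members: 7 of the 19 measured cytokine receptor genes are in another list, for example, and 5 each of the BCL2 family, p53 target and FOXO target genes. Correlations of fold changes are across genes, which are not independent replicates, and have no p-value. Each was set beside the mean of 100 simulations with no effect.

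The rule for named genes was also fixed beforehand. It takes Fos and Dusp1 in every group, and up to 10 genes with the largest rise and fall per comparison among those past the test with at least 5 FPKM and replicates that do not overlap. It takes up to 4 called members per list, or 2 by level where no member passed. For lone libraries it takes up to 10 genes on each side. Predicted genes and clone names were counted and not named, except where the interaction passed the test, and some genes that the rule takes are left out of the text. Sex-linked genes other than Eif2s3y, Ddx3y and Xist, histone genes other than Hist1h2bc, Eif3j2, Slc38a10 as an example of exact 0s, and Hmox1, Fth1 and Ftl1 in the lone libraries were chosen after their values were seen. Gene positions come from GENCODE vM21.

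The tests were run on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 11442. The changed genes were drawn from those with at least 5 FPKM in untreated cells. Lower genes were not tried, so their recovery is unknown. For imatinib against untreated cells, 90% of the 2-fold and 99% of the 4-fold genes were recovered, with 10 false calls. For the interaction of imatinib and DFC+BCI these were 78% and 96%, with 5 false calls. With no change simulated, the rule for lone libraries still called 13 genes for each comparison of labelled-deleted with wild-type libraries, 29 for imatinib in the labelled-deleted pair and 11 for BCR/ABL against vector. Alternatives tried were pseudocounts of 0.1 and 2, other filters, median-ratio scaling, quantile normalization, other settings of limma's moderation, fits on fewer groups, and each replicate left out in turn. Alternatives added after the data were seen were a block by column letter, leaving out 46 short RNA genes, leaving out the 3 lone libraries, a covariate from the shape of the low values, and other filters on histone genes. That covariate separates the vector library, both labelled-deleted libraries, the first untreated library and imatinib+DFC+BCI library a from the other 6, so it overlaps with the lone groups.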

Results

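Expression of 11442 genes was measured by RNA sequencing in Kit+ bone marrow cells, a population enriched for blood stem and progenitor cells. The cells carried BCR/ABL, the fusion kinase of chronic myeloid leukaemia, or a vector control. The series asks whether drugs against FOS and Dusp1 act as deletion of both genes does in such cells. Wild-type BCR/ABL cells were untreated, or treated with imatinib (an inhibitor of the BCR/ABL kinase), with DFC+BCI, or with all 3 drugs, with 2 libraries in each of these 4 groups. The vector control and the untreated and imatinib-treated libraries labelled deleted for c-Fos and Dusp1 have 1 library each, so their values have no replicate check. The deposited FPKM summed to 459559 to 529427 per library, and 10763 to 10987 genes reached 1 FPKM. Replicates correlated at 0.986 to 0.990 across genes, with 21 to 28 genes differing 2-fold between them. Read depth is unknown.

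**Figure D1:**
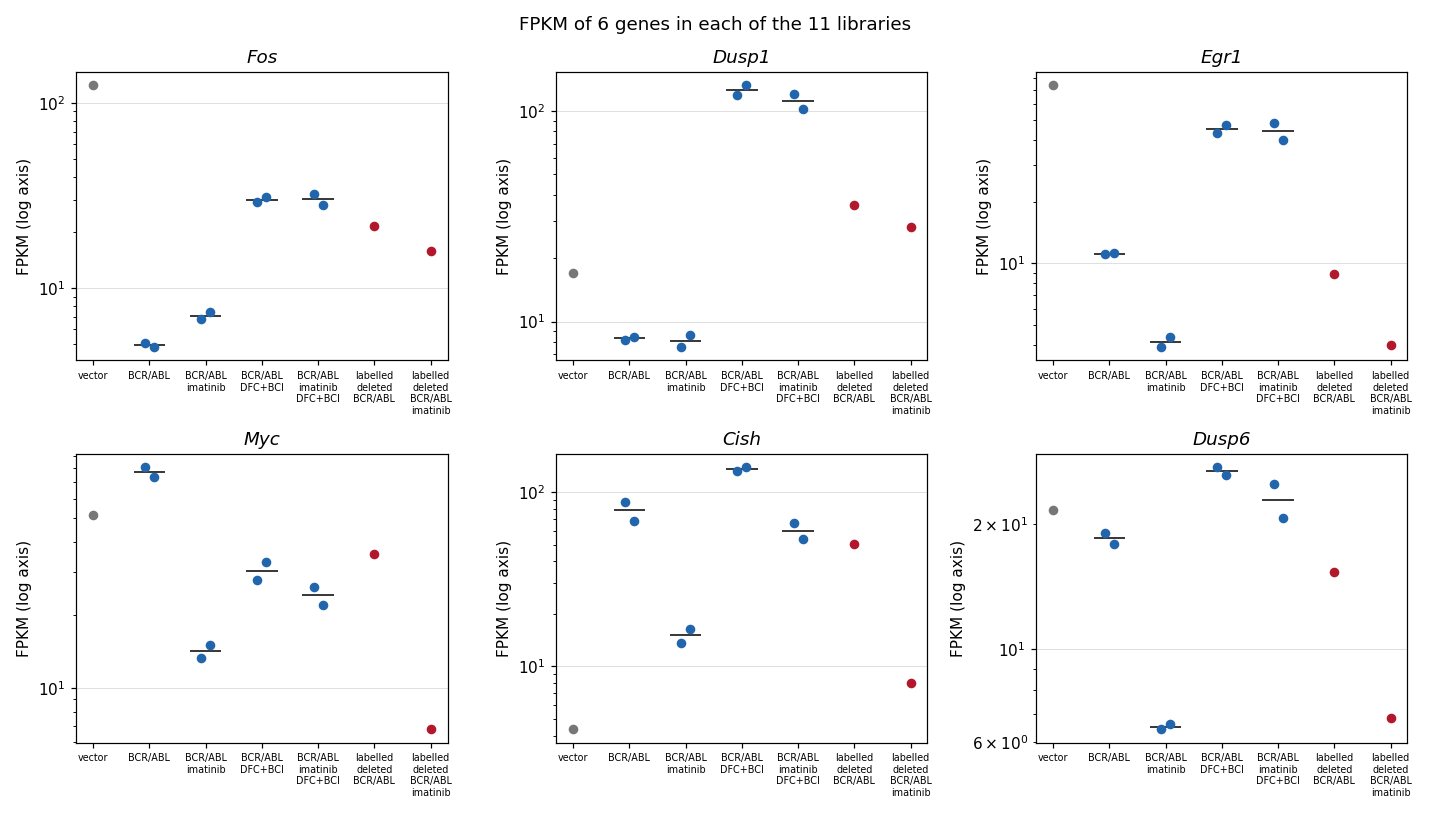
FPKM (log axis) of Fos, Dusp1, Egr1, Myc, Cish and Dusp6 in each of the 11 libraries, grouped by treatment and label; each point is a library and bars are means of groups with 2 libraries. Fos lies between 15.9 and 30.2 FPKM as a group mean in the DFC+BCI groups and the libraries labelled deleted, above the untreated mean of 4.95.

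Fos and Dusp1, the targets of the deletion as genes and of the drugs as proteins, were higher and not lower in the libraries labelled deleted. Fos (chromosome 12, 85473890 to 85477273 in GRCm38, plus strand) encodes a subunit of the AP-1 transcription factor. Its level was 4.95 ± 0.199 FPKM (SD, n = 2) in untreated BCR/ABL cells, 124.9 FPKM in the vector library, and 21.6 and 15.9 FPKM in the untreated and imatinib-treated libraries labelled deleted. Dusp1 (chromosome 17, 26505590 to 26562128, minus strand) encodes a phosphatase that switches off MAP kinases. It stood at 8.34 ± 0.171 FPKM (SD, n = 2) in untreated cells, 16.9 FPKM in the vector library, and 35.7 and 28.1 FPKM in the libraries labelled deleted. These gene-level values do not show the loss that the label names, so each direction below is that of the library labelled deleted. A gene-level value does not show which part of an allele gave the reads, so it cannot say whether the genes were deleted. DFC+BCI raised Fos to 30.0 ± 1.30 FPKM (log2 fold change 2.38, SE 0.0861, adjusted p = 6.5e-06) and Dusp1 to 126.2 ± 9.33 FPKM (3.77, SE 0.101, adjusted p = 2.63e-06; SD, n = 2 each). With all 3 drugs they reached 30.2 ± 3.12 and 111.0 ± 12.9 FPKM (SD, n = 2 each). RNA levels do not measure whether DFC+BCI inhibited the FOS and Dusp1 proteins. Imatinib alone left Fos at 7.10 ± 0.445 FPKM (log2 fold change 0.45, SE 0.0861, adjusted p = 0.0535) and Dusp1 at 8.09 ± 0.758 FPKM (-0.04, SE 0.101, adjusted p = 0.934), both short of the threshold.

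Imatinib for 4 h was compared with untreated cells. The vector library was not given imatinib, so effects through BCR/ABL cannot be told apart from effects through other targets. No group is labelled as treated with vehicle alone. Many STAT5 targets and ERK feedback genes fell, with some genes of MYC and ribosome biogenesis and of the interferon response, and some FOXO targets, which growth signalling holds back, rose. The lists passed camera with a preset correlation, and none passed with an estimated one (adjusted p = 0.0737 to 0.229 with an estimated correlation). By fry these lists passed (adjusted p = 0.00171 to 0.0362). Myc fell from 77.4 ± 4.94 to 14.2 ± 1.20 FPKM (SD, n = 2 each), a log2 fold change of -2.37 (SE 0.114, adjusted p = 0.000254). Of 11442 genes, 55 rose and 186 fell.

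Of 15 measured STAT5 target genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone). Among them were Cish (log2 fold change -2.30), Socs1 (-2.14) and Pim1 (-1.54), and the cytokine gene Osm (-2.01). Id1 fell by 2.25, and outside the list the cytokine gene Lif fell by 1.98 and the lipase gene Lipg by 1.71. The list passed camera (adjusted p = 1.29e-15; adjusted p = 0.0737 with an estimated correlation). The list of ERK feedback genes holds genes linked to ERK signalling, only some of which dampen it. Of 21 measured, 9 fell and 1 rose (12 and 1 adjusted over the list alone), including Dusp6 (-1.37), Phlda1 (-1.10), Dusp4 (-0.89) and Spry4 (-0.85). Camera gave an adjusted p of 1.51e-08 for the list (adjusted p = 0.229 with an estimated correlation). Of 24 genes of MYC and ribosome biogenesis, 3 fell (7 adjusted over the list alone): Nop2 (-0.65), Rrs1 (-0.59) and Polr1b (-0.53), with adjusted p = 1.73e-09 by camera and adjusted p = 0.229 with an estimated correlation. Among 20 interferon response genes, 5 fell (11 adjusted over the list alone), such as Ifit1 (-0.82), Usp18 (-0.55), Rsad2 (-0.45) and Mx1 (-0.44), with adjusted p = 9.46e-11 and adjusted p = 0.0922 with an estimated correlation. Il6 (-1.06) and Hbegf (-0.99) were the 2 of 17 AP-1 linked genes that fell, also 2 when adjusted over the list alone (camera adjusted p = 1.93e-05; adjusted p = 0.229 with an estimated correlation).

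Of 19 FOXO target genes, 4 rose (10 rose and 2 fell adjusted over the list alone): the repressor Bcl6 (log2 fold change 1.56), Ccng2 (0.96), the cell cycle inhibitor Cdkn1b (0.68) and Sesn1 (0.46). The list passed camera (adjusted p = 1.67e-07; adjusted p = 0.0737 with an estimated correlation). Bcl6 is also on the list of STAT5 targets, where it was the 1 member that rose. Other genes that rose were Klhl24 (1.14), Pnrc1 (0.90), Pdcd4 (0.85), Crebrf (0.85), Trp53inp1 (0.81) and Mettl7a1 (0.79). Erythroid markers passed camera upward with no member past the test (median 0.26, adjusted p = 0.00874, and 0.0646 without imatinib library a; adjusted p = 0.224 with an estimated correlation), and 2 members, Hbb-bt (0.16, adjusted p = 0.539) and Tfrc (-0.13, adjusted p = 0.412), show their spread. The list of the BCL2 family, which sets the threshold for cell death, did not pass camera (adjusted p = 0.708), with 2 of 15 members up and 3 down. Among them, the survival genes Bcl2l1 (-0.76) and Bcl2a1a (-0.67) fell, and the death-promoting Bmf (0.49) and Pmaip1 (0.40) rose. Egr1 (-1.24), Xbp1 (-0.72), the chemokine gene Ccl3 (-0.90), Hk2 (-0.58), Il4ra (-0.71) and Plk3 (-0.53) fell too, and Btg2 (0.51), Nr4a1 (0.44), Dnajb4 (0.58) and Dnajb9 (0.46) rose. No member of the G2/M, S phase, ribosomal protein or cell type lists passed the test. Short RNA genes with unstable values were also called: Snora15 and Snora52 lower, and Snora34, which was listed at 0 in both untreated libraries and at 25.1 and 38.6 FPKM with imatinib.

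The number of genes called depends on the fit, with 27 when only the 2 groups compared were fitted and 122 with no filter, and on each library: 55 without imatinib library a, 68 without imatinib library b, 65 and 72 without the first and second untreated library, and 100 to 112 without any of the DFC+BCI or 3-drug libraries. Of 48 named genes 22 held in all 8 of these fits, and the calls of Bmf, Dnajb4, Il4ra, Mx1, Nr4a1, Plk3, Pmaip1 and Rrs1 held in none of them (adjusted p up to 0.231, without imatinib library a), while all 48 kept their direction.

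DFC+BCI against untreated cells asks what the inhibitor pair does alone. Lists of heat shock genes, ATF4 targets and immediate early genes went up within 4 h, and stem and progenitor, neutrophil, mast cell and G2/M lists went down. These lists passed camera with a preset correlation, and none passed with an estimated one (adjusted p = 0.241 to 0.31 with an estimated correlation). By fry these lists passed (adjusted p = 8.36e-05 to 0.00447). Hspa1a, an inducible heat shock gene, went from 0.284 ± 0.0432 to 206.1 ± 16.4 FPKM (SD, n = 2 each; log2 fold change 7.33, SE 0.120, adjusted p = 4.12e-07), and its copy Hspa1b changed by 7.18. In total 2041 genes rose and 2107 fell, 313 and 58 of them at least 2-fold.

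Immediate early genes, which answer signals without new protein synthesis, rose in 21 of 25 cases and fell in 2, with equal numbers adjusted over the list alone. They include Jun (log2 fold change 3.44), Zfp36 (2.92), Maff (2.79) and Atf3 (2.48), and the list passed camera (adjusted p = 3.06e-13; adjusted p = 0.241 with an estimated correlation). Myc, a member of this list, fell by 1.32. Of 21 ERK feedback genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), among them Dusp1 (3.77), Dusp16 (2.18), Phlda1 (2.15) and Dusp4 (1.84), with adjusted p = 1.29e-08 and adjusted p = 0.241 with an estimated correlation. Of 17 heat shock genes 11 rose (13 adjusted over the list alone), with Dnajb4 at 1.79 and Bag3 at 1.71 (adjusted p = 9.26e-08; adjusted p = 0.241 with an estimated correlation). Of 19 targets of ATF4, the factor of the integrated stress response, 9 rose (13 adjusted over the list alone): Chac1 (4.23), Ddit3 (3.15), Trib3 (2.17) and Sesn2 (2.16) led (adjusted p = 1.97e-06; adjusted p = 0.241 with an estimated correlation). Ppp1r15a, which ends that response, rose by 3.03. NRF2 targets, which handle oxidative stress, were split, 9 of 20 rising and 4 falling (9 and 5 adjusted over the list alone). Osgin1 (2.71), Hmox1 (1.71), Srxn1 (1.53) and Gclc (1.32) rose most (camera adjusted p = 0.0469, and 0.0875 without the second untreated library; adjusted p = 0.417 with an estimated correlation).

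Targets of NF-kB, p53 and FOXO factors also went up as lists. Among 20 NF-kB targets 14 rose and 2 fell, equal numbers adjusted over the list alone, including Cxcl2 (log2 fold change 3.79), Cxcl1 (2.35), Ptgs2 (2.02) and Nfkbiz (1.99; adjusted p = 7.66e-06; adjusted p = 0.241 with an estimated correlation). Among 20 p53 targets 11 rose and 4 fell, again equal numbers adjusted over the list alone, led by Gdf15 (3.77), Plk2 (2.95) and Plk3 (2.43), with adjusted p = 0.00139 and adjusted p = 0.241 with an estimated correlation. Of 19 FOXO targets 10 rose and 1 fell (10 and 2 adjusted over the list alone), with Gadd45a (2.12), Irs2 (1.69), Txnip (1.36) and Ccng2 (1.31) at the top (adjusted p = 7.55e-05; adjusted p = 0.241 with an estimated correlation). In the BCL2 family, whose list did not pass, the death-promoting genes Bbc3 (2.04), Pmaip1 (1.82) and Bcl2l11 (1.21) rose and Bcl2a1a (-0.94) fell. Insig1 (1.73) and Hmgcs1 (0.63) of cholesterol supply rose, as did Ddit4 (2.54), Vegfa (1.52), Dnajb9 (2.36), Herpud1 (1.69), Hbegf (2.66), Fosl1 (1.53) and the histone gene Hist1h2bc (3.28). STAT5 targets went both ways: Socs3 (1.97), Osm (0.92) and Cish (0.79) rose, and Socs1 (-0.99) fell. Ifit1 (-1.25), Ifit3 (-0.87) and Gbp2 (-0.64) of the interferon list fell and Mx2 (0.70) rose. Ccne1 (-0.60) and Rrm1 (-0.45) of the S phase list fell, and Cdc6 (0.50) and Cdt1 (0.66) rose.

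Cell cycle and lineage genes fell by less. Of 22 G2/M genes 13 fell (14 adjusted over the list alone), among them Ccnb1 (log2 fold change -0.62), Plk1 (-0.59), Cdk1 (-0.58) and Aurkb (-0.57), with adjusted p = 0.000115 and adjusted p = 0.31 with an estimated correlation. Of 13 stem and progenitor markers 8 fell and 1 rose, equal numbers adjusted over the list alone, including Myb (-0.80), Ly6a (-0.79), Kit (-0.70) and Gata2 (-0.69; adjusted p = 0.006; adjusted p = 0.3 with an estimated correlation). Of 17 neutrophil lineage markers 9 fell (10 adjusted over the list alone), such as Gfi1 (-0.95), S100a8 (-0.79), Ctsg (-0.70) and Ms4a3 (-0.66), with adjusted p = 0.000323 and adjusted p = 0.241 with an estimated correlation. Monocyte and macrophage markers fell in 7 of 15 cases and rose in 2 (8 and 2 adjusted over the list alone), with Cd14 (-0.73), Fcgr1 (-0.65) and Lyz2 (-0.53) down (adjusted p = 0.0252; adjusted p = 0.351 with an estimated correlation). Of 13 mast cell and basophil markers 6 fell, equally many adjusted over the list alone, led by Il1rl1 (-0.87; adjusted p = 0.0346; adjusted p = 0.241 with an estimated correlation). Their camera call was lost with the covariate from the low values (adjusted p = 0.057) and under quantile normalization (0.0552). Eosinophil markers Ear6 (-1.34), Ear2 (-1.29) and Prg2 (-0.29) were 3 of 7 that fell (4 adjusted over the list alone; adjusted p = 0.0326; adjusted p = 0.241 with an estimated correlation). Of 13 megakaryocyte markers 5 fell, equally many adjusted over the list alone, with Gp5 at -1.34 (adjusted p = 0.018; adjusted p = 0.442 with an estimated correlation). The receptor genes Csf2rb (-0.59) and Csf2rb2 (-0.52), the erythroid genes Tfrc (-0.45) and Car1 (-0.44), Tcf7 (-0.51) and Pecam1 (-0.43) fell as well. Other large falls were in Clec2d (-2.02), Apol7c (-2.04), the pseudogene Apoo-ps (-2.08) and Eif3j1 (-3.92), whose near copy Eif3j2 was at 70.9 and 77.8 FPKM with DFC+BCI and at 38.3 and 35.8 FPKM untreated. The short RNA genes Snord16a, Snora52, Snora7a and Snora81 were also called lower.

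Among 27 cytoplasmic ribosomal protein genes Rpl23 (-0.31) and Rps4x (-0.24) fell, and no member passed adjusted over the list alone. That list's camera call (adjusted p = 0.0493; adjusted p = 0.631 with an estimated correlation) was lost without the first untreated library (adjusted p = 0.408), and quantile normalization turned its direction (adjusted p = 0.338; 0.00329 to 0.631 over 14 alternatives). The calls for monocyte, eosinophil and megakaryocyte markers were each lost without an untreated library (adjusted p = 0.0875 and 0.0774 without the second, 0.065 without the first), and 2134 genes were called without DFC+BCI library a and 2530 without library b. Median and mean differed in sign for the lists of cholesterol synthesis, of glycolysis and hypoxia and of AP-1 linked genes, and camera ran against both for the BCL2 family, and none of these 4 lists passed.

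All 3 drugs together, against untreated cells, raised 1964 genes and lowered 1790. Hspa1a (log2 fold change 7.72, SE 0.120, adjusted p = 2.76e-07), Hspa1b (7.59), Chac1 (4.27), Hist1h2bc (3.62), Dusp1 (3.58), Cxcl2 (3.57), Gdf15 (3.54), Jun (3.51), Ddit3 (3.25) and Ppp1r15a (3.18) rose most. Clec2d (-2.46), Socs1 (-2.12) and Apol7c (-1.90) fell most among genes other than predicted and short RNA genes. Heat shock genes rose in 13 of 17 cases (14 adjusted over the list alone), with Hspb1 at 2.61 and Dnajb1 at 2.15 (adjusted p = 6.84e-10; adjusted p = 0.286 with an estimated correlation). Immediate early genes rose in 20 of 25 cases and fell in 2 (21 and 2 adjusted over the list alone), Fosb (2.56) among them, with adjusted p = 5e-13 and adjusted p = 0.286 with an estimated correlation. Il6 (-1.39), Id1 (-1.03) and Il2ra (-0.90) fell, as did Ifit1 (-1.61) and Ifit2 (-0.71). Of 28 lists 15 passed camera: ERK feedback genes and targets of ATF4, p53, NF-kB and FOXO factors went up beside the heat shock and immediate early genes. G2/M genes, cytokine receptor genes, and stem and progenitor, neutrophil, monocyte, mast cell, eosinophil and megakaryocyte markers went down, Gp5 (-1.41), Il1rl1 (-1.05), Gfi1 and Ear6 (-1.65) among them. With an estimated correlation, the adjusted p of these 15 lists ran from 0.286 to 0.467. The call for monocyte and macrophage markers was lost in 6 of 8 fits that left out 1 library (adjusted p up to 0.163, without the second untreated library), that for megakaryocyte markers in 2 (0.138 without 3-drug library b) and that for eosinophil markers in 1 (0.0758 without the second untreated library). Without 3-drug library a 2461 genes were called, and without library b 2317. Lists of cholesterol synthesis, glycolysis and hypoxia, BCL2 family, AP-1 linked and erythroid genes, none of which passed, had a mean above and a median below 0.

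Against imatinib alone, the question is what the inhibitor pair adds to imatinib, and several genes that imatinib had lowered were higher with all 3 drugs. Egr1 (log2 fold change 3.12, SE 0.103), Phlda1 (2.94), Dusp4 (2.30), Socs3 (2.13), Osm (2.06), Cish (1.93), Pim1 (1.58) and Hbegf (3.25) rose, and Myc rose from 14.2 ± 1.20 to 24.0 ± 2.83 FPKM (SD, n = 2 each; 0.72, SE 0.114, adjusted p = 0.00317), still below the untreated level. In total 2127 genes rose and 1828 fell. Klhl24 was -0.14 (adjusted p = 0.2), Bcl6 fell (-1.13, SE 0.0918, adjusted p = 0.00017) and Ccng2 rose (0.33, SE 0.0663, adjusted p = 0.00827). Of 15 STAT5 targets 9 rose and 2 fell, equal numbers adjusted over the list alone (camera adjusted p = 0.00426; adjusted p = 0.259 with an estimated correlation). Of 24 genes of MYC and ribosome biogenesis 9 rose and 1 fell, equal numbers adjusted over the list alone, including Nop2 (0.66), Gnl3 (0.59), Nop56 (0.55) and Rrs1 (0.52; adjusted p = 0.0203; adjusted p = 0.495 with an estimated correlation). Of 21 ERK feedback genes 17 rose (18 adjusted over the list alone; adjusted p = 7.66e-12; adjusted p = 0.222 with an estimated correlation). Among the largest rises were Hspa1a (7.82), Hspa1b (7.51), Chac1 (4.22), Cxcl2 (3.73), Jun (3.65), Dusp1 (3.62), Hist1h2bc (3.43), Ppp1r15a (3.27) and Gdf15 (3.22). Lpar6 (-2.01), Clec2d (-2.67), Apol7c (-1.63), the nuclear RNA Neat1 (-1.63), Rab26os (-1.65), Ear6 (-1.60), Myb (-0.96), S100a8 (-1.11) and Epor (-0.93) fell. Of 28 lists 16 passed camera, 8 in each direction. With an estimated correlation none of them passed, the adjusted p running from 0.222 to 0.495. Without 3-drug library b the call for megakaryocyte markers was lost (adjusted p = 0.127) and 2559 genes were called, and without imatinib library a 2563.

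Adding imatinib to DFC+BCI changed 13 genes by the test, and the cytokine genes Lif, Osm, Il6 and Il1f9 were 4 of the 12 that fell. Lif fell from 15.6 ± 0.649 to 7.73 ± 0.168 FPKM (SD, n = 2 each; log2 fold change -0.93, SE 0.0765, adjusted p = 0.0135). Osm (-0.87), Il6 (-0.77), Il1f9 (-0.69), the STAT5 target Socs2 (-0.53), Tma16 (-0.52) and Serpina3g (-0.44) fell too. Of 15 STAT5 targets 2 fell (10 fell and 1 rose adjusted over the list alone), with camera adjusted p = 7.96e-12 and adjusted p = 0.243 with an estimated correlation. Cish was 135.6 ± 4.62 FPKM with DFC+BCI and 60.2 ± 8.57 FPKM with all 3 drugs (SD, n = 2 each), short of the threshold (-1.17, SE 0.147, adjusted p = 0.0584). Heat shock genes shifted up (median 0.15, 5 adjusted over the list alone; adjusted p = 1.37e-05; adjusted p = 0.377 with an estimated correlation), as did ribosomal protein genes (median 0.10; adjusted p = 0.00143; adjusted p = 0.614 with an estimated correlation). The ribosomal call was also lost with the covariate from the low values (adjusted p = 0.11) and under quantile normalization (0.503). ERK feedback genes and targets of NF-kB, p53 and NRF2, interferon response genes and AP-1 linked genes shifted down, with medians from -0.13 to -0.04. Of these, 5 ERK feedback, 3 NF-kB, 2 NRF2 and 1 AP-1 linked genes fell adjusted over the list alone, 1 of the NF-kB and 1 of the AP-1 linked genes over all genes (adjusted p between 8.18e-05 and 0.0274; adjusted p = 0.377 to 0.543 with an estimated correlation). By fry none of the lists passed (0, with 5 at an unadjusted p under 0.05), against 9 by camera. In the other comparisons fry passed 7 lists for imatinib and 22 for DFC+BCI. It passed 21 for all 3 drugs against untreated cells and 25 against imatinib. In total 1 gene rose (Eif3j1, 3.88, whose reads may be divided with Eif3j2) and 12 fell, Snora16a among them. Each of the 8 fits that left out 1 library called 7 genes or fewer, and 1 gene without DFC+BCI library a or 3-drug library a. Lif was called in 4 of these fits, Il6 in 4 and Osm in 2, with adjusted p up to 0.22, 0.22 and 0.318, and Il1f9, Socs2, Tma16 and Serpina3g in none (adjusted p up to 0.282, 0.491, 0.414 and 0.414). A block by column letter on the 6 lettered libraries called 0 genes by limma (712 at an unadjusted p under 0.05), and those libraries without the block gave 6. Of the 9 list calls 4 held in all 8 fits. The interferon call was lost in 2 (up to 0.19 without 3-drug library a), NRF2 in 2 (0.181) and p53 and AP-1 linked genes in 1 each (0.0614 for both), up to those values without DFC+BCI library a, and the ribosomal call in 1 (0.0845 without 3-drug library a). Median and mean differed in sign for cytokine receptor genes, and camera ran against both for erythroid markers; neither list passed.

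The interaction asks whether imatinib acts differently with the inhibitors present. It did for 17 genes, 10 with a higher and 7 with a lower effect of imatinib in the presence of DFC+BCI. Myc fell by 2.37 with imatinib alone and was -0.33 when imatinib was added to DFC+BCI (adjusted p = 0.487), an interaction of 2.04 (SE 0.162, adjusted p = 0.0133). Lipg (1.75), Egr1 (1.19), Osm (1.14), Dusp6 (1.14) and Lif (1.05) had positive interactions. The FOXO targets Bcl6 (-1.32) and Ccng2 (-0.98) and Klhl24 (-0.93) had negative ones. DFC+BCI alone had already lowered Myc and raised Ccng2. For Myc and Ccng2, each treatment alone thus moved the gene the same way, and the joint effect fell short of the sum. Genes of MYC and ribosome biogenesis (camera adjusted p = 3.64e-08; adjusted p = 0.297 with an estimated correlation) and STAT5 targets (2.96e-06; adjusted p = 0.297 with an estimated correlation) had positive interactions as lists. FOXO targets had a negative one (3.67e-08; adjusted p = 0.113 with an estimated correlation). Adjusted over the list alone these were 5 of 24, 9 of 15 with 1 negative, and 4 of 19. Bcl6 is on both the STAT5 and the FOXO list, and was the 1 negative STAT5 target. Interferon response, heat shock and ERK feedback genes also passed upward and p53 targets and erythroid markers downward (adjusted p between 0.00014 and 0.033; adjusted p = 0.297 to 0.633 with an estimated correlation). By fry only 3 lists passed: STAT5 targets (adjusted p = 0.0474), interferon response genes (0.0474) and FOXO targets (0.0249). Genes of MYC and ribosome biogenesis did not pass by fry (adjusted p = 0.0707). Of the 241 genes called with imatinib alone, the 186 that fell had a median of -0.56 there and of -0.14 on top of DFC+BCI, where 144 kept their direction and 9 passed. The 55 that rose had medians of 0.49 and 0.02, and 31 kept their direction. These genes were selected in the first comparison, which enlarges their medians there. Leaving out any 1 library called 2 to 12 genes, 2 without DFC+BCI library a, and Myc held in 5 of 8 such fits (adjusted p up to 0.0683, without that library), while the erythroid call was lost in 4 (0.229 without DFC+BCI library b). Median, mean or camera differed in sign for S phase, BCL2 family, unfolded protein response, stem and progenitor, and T and NK cell lists, none of which passed.

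**Figure D2:**
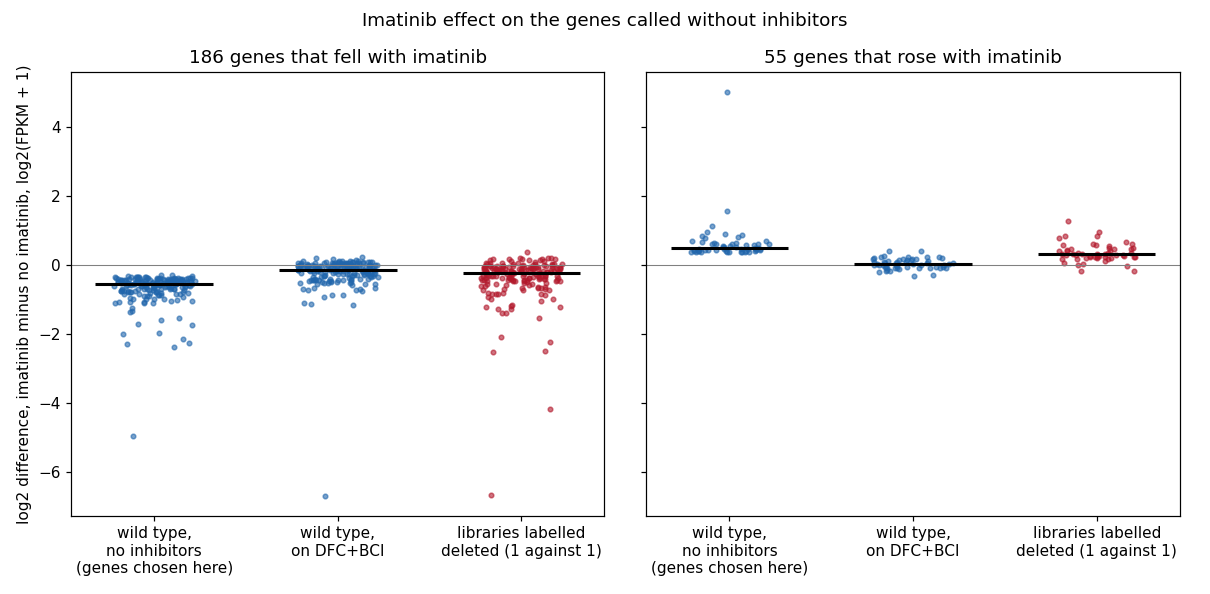
Log2 effect of imatinib on the 241 genes called with imatinib alone: without inhibitors, on DFC+BCI and in the libraries labelled deleted (y axis), for genes that fell (left) and rose (right); each point is a gene and bars are medians. The 186 genes that fell have medians of -0.56 alone, -0.14 on top of DFC+BCI and -0.23 in the libraries labelled deleted.

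The libraries labelled deleted differed from wild type in lineage genes. Without drugs, most mast cell and basophil, neutrophil and interferon response genes of the lists were lower. The medians of monocyte and macrophage markers, NRF2 targets and AP-1 linked genes were above 0, with 8 of 15, 7 of 20 and 7 of 17 members higher by the size rule. Myeloperoxidase (Mpo), a granule enzyme of neutrophils, was at 23.1 FPKM against 205.5 ± 40.0 (SD, n = 2), and Procr, a receptor on stem and endothelial cells, at 74.7 against 5.16 ± 0.0829 FPKM. By the size rule 391 genes were higher and 231 lower. The median of all genes was -0.13, and median-ratio scaling moved it to 0.01 and the counts to 537 higher and 153 lower, so list medians should be read against that shift. The balance depends on the rule: a limma contrast with the spread of the replicated groups gave 2023 higher and 3765 lower.

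Of 13 mast cell and basophil markers 10 were lower (median log2 difference -1.97, percentile 0 of 10000 random lists). Neutrophil markers were lower in 10 of 17 cases and higher in 1 (-1.31, percentile 0), and interferon response genes lower in 12 of 20 (-1.51, percentile 0). Genes of MYC and ribosome biogenesis (-0.88) and G2/M genes (-0.82) lay at percentile 0 too. STAT5 targets had a median of -0.61 (percentile 0.06), with 3 of 15 lower by the size rule. Monocyte and macrophage markers were higher in 8 of 15 cases (1.13), NRF2 targets in 7 of 20 (0.97), AP-1 linked genes in 7 of 17 with 2 lower (0.99) and immediate early genes in 7 of 25 with 1 lower (0.60), each at percentile 100. Hmox1 stood at 3021 FPKM against 381.6 ± 10.6, and the ferritin gene Fth1 at 15310 against 4549 ± 26.8 FPKM (SD, n = 2 each). Treml4 (log2 difference 3.52), Cav1 (3.45) and Ifi202b (3.66) were higher, and Myl10 (-4.99), Mgl2 (-3.70), Prg2 (-3.14), Klk1b11 (-3.05) and Ccl8 (-2.92) lower. The Y-linked genes Eif2s3y and Ddx3y were at 35.1 and 14.4 FPKM, and at most at 0.0252 and 0.0102 FPKM in the 9 other libraries. Ear10 (15.2 FPKM), Mir3074-1, Mir3473c and Mir425 were listed at 0 in both wild-type libraries, and Snora70, Snora21 and Snora16a at 0 in the library labelled deleted. Eif3j1 was at 0.178 FPKM there.

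With imatinib in both, 215 genes were higher and 146 lower in the library labelled deleted by the size rule, and 1643 and 2433 by the limma contrast. Mast cell and basophil markers (median log2 difference -1.78, 10 of 13 lower), interferon response genes (-1.20, 13 of 20 lower) and neutrophil markers (-1.11, 8 of 17 lower) were again at percentile 0. STAT5 targets had a median of -0.41 (percentile 0.17), with 1 of 15 lower. NRF2 targets (0.86, 7 of 20 higher), monocyte and macrophage markers (0.58, 2 of 15 higher) and AP-1 linked genes (0.56, 6 of 17 higher and 2 lower) were at percentile 100. Treml4 (3.48) was higher. Myl10 (-4.47), Mgl2 (-3.71), Klk1b11 (-3.37), Prg2 (-2.98), Xist (-3.14) and the mast cell protease Prss34 (-2.87) were lower. Eif2s3y (36.2 FPKM), Ddx3y (13.7 FPKM), Ear10 (13.8 FPKM), Ifi202b (8.65 FPKM), Snord96a, Mir3473c, Snord35b, Snora2b and Snora21 were listed at 0 in both wild-type libraries, and Slc38a10, Snord16a, Snora34 and Snora78 at 0 in the library labelled deleted.

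Imatinib in the pair labelled deleted, 1 library against 1, gave 12 higher and 31 lower genes. The same rule called 29 genes here with no change simulated, and 21 to 28 between replicates of a group, so many of these calls may be background. Id1 was lower (log2 difference -2.53) and Bcl6 higher (1.26), and STAT5 targets were lower in 6 of 15 cases and higher in 1 (median -0.46, percentile 0). Cish was at 8.08 against 50.6 FPKM and Myc at 6.76 against 35.7 FPKM. Immediate early genes (-0.54), AP-1 linked genes (-0.42), NF-kB targets (-0.36) and ERK feedback genes (-0.33) lay at percentile 0, and G2/M (0.28) and S phase genes (0.27) at percentile 100. Of the genes called with imatinib in wild-type cells, 159 of the 186 that fell and 51 of the 55 that rose had the same direction here. Hbb-bs (4.96), Hba-a1 (-3.52) and Eif3j1 (3.42) have near copies, Slc38a10 was listed at 0, and of the other genes named by the rule all were short RNA genes listed at 0 in 1 of the libraries. Without short RNA genes 27 genes were called.

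BCR/ABL against the vector library shows genes that differ with the oncogene, again against 1 library. By list median, STAT5 targets, genes of MYC and ribosome biogenesis, interferon response genes and neutrophil markers lay above 0, and immediate early genes and markers of monocytes, mast cells and megakaryocytes below 0, though many members did not meet the size rule. Cish was at 78.5 ± 13.9 FPKM (SD, n = 2) against 4.35 FPKM, Lipg had a log2 difference of 6.19 and the arginase gene Arg1 one of 6.38. By the size rule 380 genes were higher and 536 lower, and by the limma contrast 3155 and 3003. STAT5 targets were higher in 7 of 15 cases and lower in 1 (median 0.82), genes of MYC and ribosome biogenesis in 10 of 24 (0.96), interferon response genes in 14 of 20 (1.61), neutrophil markers in 9 of 17 with 2 lower (1.72) and p53 targets in 8 of 20 with 1 lower (0.73), each at percentile 100. Monocyte and macrophage markers were lower in 9 of 15 cases and higher in 1 (-1.48), mast cell and basophil markers lower in 7 of 13 and higher in 2 (-1.22), immediate early genes lower in 9 of 25 (-0.73), cytokine receptor genes in 9 of 19 (-0.64) and FOXO targets in 6 of 19 (-0.66), each at percentile 0. Most of these lists had a median of opposite sign in the untreated library labelled deleted against wild type, STAT5 targets (-0.61) among them. Mast cell and basophil markers had the same sign in both, as did NRF2 targets and AP-1 linked genes. Both comparisons use the untreated BCR/ABL libraries, so opposite signs may partly come from these. The cause was not tested. The stefin genes Stfa2 (7.15), Stfa2l1 (6.23), Stfa1 (6.08) and Stfa3 (5.86), the globins Hbb-bt (6.39) and Hbb-b1 (5.67), Tnfrsf9 (5.07) and Thy1 (5.03) were higher. The proteases Prss34 (-5.49) and Tpsb2 (-4.48), Apoe (-5.16), Cox6a2 (-5.06), Cx3cr1 (-4.58), Cd7 (-4.51) and Fos (-4.40) were lower, while Mir682, Snora75 and Snora34 were listed at 0 with BCR/ABL.

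**Figure D3:**
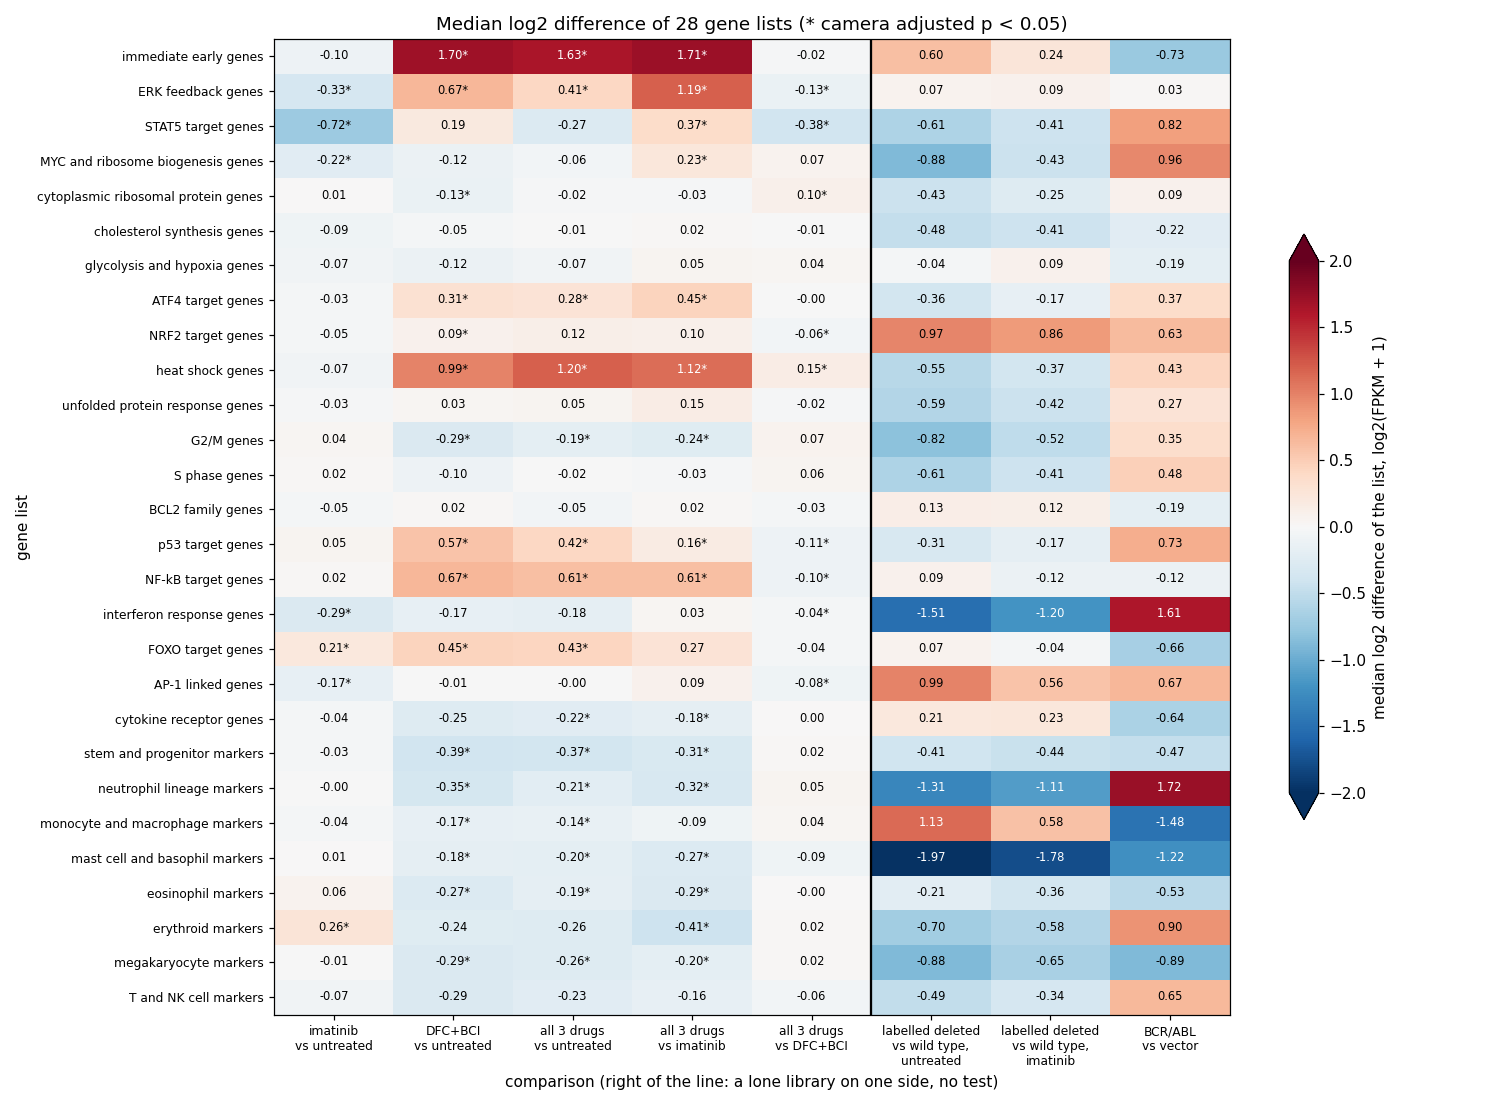
Median log2 difference of 28 gene lists (one per line) in 8 comparisons (one per column); colour runs from -2 (blue) to 2 (red), an asterisk marks camera adjusted p under 0.05, and columns right of the line have a lone library and no test. Immediate early genes have medians of 1.70, 1.63 and 1.71 in the comparisons that add DFC+BCI, and mast cell and basophil markers medians of -1.97 and -1.78 in the libraries labelled deleted.

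The series asks whether DFC+BCI and the deletion act alike. Fos and Dusp1 were higher in the libraries labelled deleted, and gene-level values cannot say whether the genes were deleted there. The values below therefore compare DFC+BCI with the libraries so labelled and cannot be read as the effect of a deletion. Immediate early genes rose as a list with DFC+BCI (adjusted p = 0.241 with an estimated correlation) and had a median of 0.60 in the untreated library labelled deleted. Mast cell and neutrophil markers and G2/M genes fell as lists with DFC+BCI (adjusted p = 0.241 to 0.31 with an estimated correlation) and had medians of -1.97, -1.31 and -0.82 in that library. NRF2 targets, split with DFC+BCI (median 0.09), had a median of 0.97 there. Heat shock genes had a median of 0.99 with DFC+BCI and of -0.55 in the library labelled deleted, and Hspa1a was at 0.457 FPKM in the latter. Monocyte and macrophage markers went the other way, with medians of -0.17 and 1.13. ATF4 targets (0.31 and -0.36) and p53 targets (0.57 and -0.31) differed in sign too. ERK feedback genes (0.665 and 0.07), FOXO (0.45 and 0.07) and NF-kB targets (0.665 and 0.09) were near 0 in that library. Of the other called lists, stem and progenitor (-0.39 and -0.41) and megakaryocyte markers (-0.29 and -0.88) were below 0 in both. So were eosinophil markers (-0.27 and -0.21) and ribosomal protein genes (-0.13 and -0.43). Of genes lower in the library labelled deleted, 111 also fell with DFC+BCI, where independent lists would share 50.4. Higher genes shared 87 against 62.8, and 6 genes rose with DFC+BCI and were lower in the library labelled deleted, against 37.1, while 68 fell with DFC+BCI and were higher in that library, against 85.4. With imatinib in all groups these were 68 against 26.3, 43 against 36.3, 11 against 24.6 and 35 against 38.6. These overlaps share their wild-type controls, and part of the excess may come from the shared controls. Without a shared library, DFC+BCI against the imatinib-treated pair gave 74 against 31.9, 44 against 34.7, 7 against 23.6 and 42 against 47.02. All 3 drugs against imatinib, set beside the untreated pair, gave 89 against 40.9, 81 against 67.0, 30 against 39.5 and 69 against 69.2 in the same order.

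Across genes, the change with DFC+BCI and the difference of the library labelled deleted correlated at 0.18, and with imatinib in all groups at 0.17. Both use the same wild-type controls, which alone gave 0.41 and 0.41 in simulations with no effect. The covariances were 0.0542 and 0.0424 against 0.0215 and 0.0218 simulated, and part of the excess of shared genes may come from the shared controls. Pairs without a shared library correlated at 0.16 and 0.10 (simulated -0.01 for each, with highest values of 0.37 and 0.31). Genes are not independent replicates, so these have no p-value. Without the second untreated library the first value was 0.257, and without imatinib library a the value with imatinib was 0.253. The pair values were 0.0935 without the first untreated library and 0.0597 without 3-drug library a.

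The effect of imatinib in wild-type cells correlated at 0.27 with that in the pair labelled deleted (simulated -0.03, highest 0.32; 0.126 without the first untreated library). Its effect on top of DFC+BCI correlated at -0.01 with that in the pair labelled deleted by Pearson's r and at 0.28 by Spearman's rho, and r was 0.359 without the short RNA genes (simulated 0.01 with them, highest 0.42). The effects of imatinib without and with DFC+BCI correlated at 0.16 by r and at 0.00 by rho (simulated 0.03; r 0.0663 without DFC+BCI library a, 0.0246 without the second and 0.236 without the first untreated library).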

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

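The interaction was planned, and the counts of fits that keep each call were made after the results were seen.

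The effect of imatinib differed with and without DFC+BCI, by limma's test of the interaction, for 17 genes. Positive values mean that imatinib lowered a gene less, or raised it more, when DFC+BCI was present. Myc had an interaction of 2.04 (SE 0.162, adjusted p = 0.0133), and the lipase gene Lipg one of 1.75 (SE 0.115, adjusted p = 0.00534). DFC+BCI alone had already lowered Myc. Egr1, an immediate early gene, had 1.19 (adjusted p = 0.048), the ERK phosphatase gene Dusp6 1.14 (adjusted p = 0.0363), and the cytokine genes Osm and Lif 1.14 (adjusted p = 0.0363) and 1.05 (adjusted p = 0.0343). Gapt had 0.88 (adjusted p = 0.0468), the survival gene Bcl2a1a 0.77 (adjusted p = 0.0363) and Fam60a 0.77 (adjusted p = 0.0363). Negative values were found for the repressor gene Bcl6 (-1.32, adjusted p = 0.0299), Ccng2 (-0.98, adjusted p = 0.0296), Klhl24 (-0.93, adjusted p = 0.0467), the phosphodiesterase gene Pde4b (-0.92, adjusted p = 0.0468), 2810474O19Rik (-0.81, adjusted p = 0.0363) and G2e3 (-0.73, adjusted p = 0.0487). The values of 2 further genes are uncertain. Eif3j1 (5.37, adjusted p = 0.0133) has the near copy Eif3j2, and the short RNA gene Snora34 (-5.01, adjusted p = 0.00138) was above 0 only in both imatinib libraries and the vector library, so its value depends on the pseudocount.

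Leaving out 1 library at a time in 8 fits kept the direction of each of these genes that the naming rule covers. The call for Snora34 held in 8 fits, that for Lipg in 7, and those for Myc and Eif3j1 in 5. Egr1, Osm, Dusp6 and Ccng2 held in 1, and Lif, Gapt, Bcl2a1a, Fam60a, Bcl6, Klhl24, Pde4b and G2e3 in none. The highest adjusted p was 0.284, for G2e3 without DFC+BCI library a. At an unadjusted p under 0.05, 1409 genes had an interaction, where 572 are expected by chance.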

How the results depend on the processing

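The block by column letter, the covariate from the low values, quantile normalization of the list tests, and the fits without short RNA genes or without the 3 lone libraries were chosen after the data were seen.

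For named genes, 11269 values under alternatives kept their side of the threshold or, without a test, stayed within the replicates' spread. Another 578 lost and 7 gained the threshold, 349 without a test were counted as moved, and no called value changed sign. Sign changes of values not called were not counted. Minimums of 1 and 20 FPKM, a difference of 1.5 and leaving out short RNA genes alter no difference of a lone library. Of the 349, 22 under each of the first settings and 6 under the last were counted as moved only because their replicates' spread was 0. Unchanged lone-library values there show nothing either. For gene lists, 3052 were counted as unchanged, 132 lost and 60 gained the threshold, 170 moved and 2 called ones changed sign. Those 2 were the ribosomal protein genes with DFC+BCI under quantile normalization (adjusted p = 0.338, upward; 0.00329 to 0.631 over 14 alternatives) and the median of glycolysis and hypoxia genes, library labelled deleted against wild type with imatinib, without imatinib library a (-0.0356, and 0.129 without library b). The cause of these and the changes below was not tested.

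With no filter, imatinib called 122 genes and the interaction 2, over more genes tested. Fits on only the groups compared, with fewer degrees of freedom, called 27 genes for imatinib and 7 for all 3 drugs against DFC+BCI. The interaction called 11 genes after quantile normalization, 7 without the variance trend and 4 with the covariate from the low values. With 1 replicate left out, where the lone library is assumed to vary like the other groups, counts ran from 55 to 112 for imatinib, 2134 to 3996 for DFC+BCI, 2317 to 3581 for all 3 drugs against untreated, 2559 to 4021 against imatinib, 1 to 7 against DFC+BCI and 2 to 12 for the interaction. Leaving out the 3 lone libraries or the short RNA genes kept these counts within 1.5 times. Of 28 lists in 6 comparisons, camera called 71 cases, 0 with an estimated correlation (18 at an unadjusted p under 0.05), 78 with fry, and 66 to 74 with 1 replicate left out. Calls lost with the covariate (adjusted p) or under quantile normalization include mast cell (0.057; 0.0552) and megakaryocyte markers (0.0741 with the covariate) and monocyte markers (0.215 under quantile normalization) with DFC+BCI. Monocyte markers with all 3 drugs against untreated were lost with both (0.0559; 0.275), and the interferon call against DFC+BCI (0.0819) and the erythroid interaction (0.0854) with the covariate.

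No paired analysis was possible because the untreated columns carry neither letter nor replicate number, for the 4 comparisons that use them. For the other 2, a block by the column letter on the 6 lettered libraries called, by limma, 0 genes for all 3 drugs against DFC+BCI (712 at an unadjusted p under 0.05) and 2864 against imatinib. Without the block those libraries gave 6 and 4014. Differences between letters correlated at -0.0685 (DFC+BCI and 3 drugs), -0.138 and -0.0945 between groups, and without short RNA genes at 0.118, -0.117 and -0.445, so whether the letters pair the libraries stays open. The planned count test was not run because the values are not counts.

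For lone libraries, a minimum of 20 FPKM gave 374 genes (labelled deleted against wild type, untreated), 198 (imatinib), 27 (imatinib in the pair labelled deleted) and 509 (BCR/ABL against vector). A difference of at least 1.5 gave 233, 137, 25 and 409. Without short RNA genes, imatinib in the pair labelled deleted gave 27. A limma contrast that borrows the spread of the replicated groups called 5788, 4076 and 6158 genes for the comparisons other than that pair. Of these 2023, 1643 and 3155 were higher, so the balance of directions turned against the size rule in each of these 3.

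Correlations with 1 replicate left out ran from 0.165 to 0.257 (DFC+BCI and labelled deleted), 0.127 to 0.253 (with imatinib), 0.0935 to 0.202 and 0.0597 to 0.133 (no shared library), 0.126 to 0.332 (imatinib, wild type and labelled deleted), -0.0354 to 0.0293 (imatinib on DFC+BCI and labelled deleted) and 0.0246 to 0.236 (imatinib without and with DFC+BCI). Spearman's rho was 0.0662, 0.278 and 0.00356 for the 4th, 6th and 7th of these, and r without short RNA genes 0.0739 and 0.359 for the 4th and 6th. Depth is unknown, so it cannot be said which low genes it limits.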

Other observations

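Tests of explanations were written before those tests were run. The comparison of Ddx3y between libraries, the test of S phase as the whole cause, and the counts of histone genes under other filters were added after results were seen. The tests of early genes, cell types and S phase reuse lists and libraries of the Results. They are therefore not independent support. The histone genes, sex-linked genes and short protein-coding genes were chosen after the data were seen.

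Histone genes rose with DFC+BCI. Of 39 measured core and linker histone genes, 31 rose with DFC+BCI (median log2 fold change 1.29), 35 with all 3 drugs against untreated cells (1.44) and 34 against imatinib (1.41). Imatinib alone gave a median of 0.09, and the libraries labelled deleted medians of 0.06 and 0.04. Hist1h2bc rose from 14.0 ± 0.357 to 144.4 ± 1.92 FPKM (SD, n = 2 each). In untreated cells 33 of the 39 were under 1 FPKM, and 10 reached 5 FPKM in the higher group, so the filter could favour genes that are high with DFC+BCI. Of 13 genes kept by a filter on the libraries without DFC+BCI, 10 rose (median 1.64), and the 67 histone genes in the table had a median of 0.75 with no filter. Near copies may have had reads divided between them. Replication-dependent histone mRNAs lack a poly(A) tail, and kits of the type used here usually select for one.

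As explanations for the histone genes, a larger share of cells in S phase and a general gain of short transcripts were tested. The S phase list had a median of -0.0991 (-0.216 to 0.052 with 1 library left out), with members going both ways, so a smaller contribution of S phase cannot be told apart from none. For S phase as the whole cause, a bound set after the values were seen asked for at least 0.5 of the histone median. The highest S phase median, 0.052, is below 0.5 of the lowest histone median (1.23) with 1 library left out. That argues against S phase as the whole cause only if both sets of genes follow the share of such cells to a like degree, which was not tested. Short transcripts argue against the other: 466 protein-coding genes outside the histone families with a longest transcript under 1000 bases had a median of -0.215 (-0.297 to -0.118 with 1 library left out).

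The libraries labelled deleted also differ from the others in sex-linked genes. Kdm5d was at 4.28 to 4.71 FPKM and Uty at 4.13 to 4.48 FPKM in both, and at most at 0 and 0.00747 FPKM in the 9 others. Ddx3y was at 13.7 to 14.4 FPKM in both, and Xist at 6.00 to 6.54 FPKM against 46.6 to 84.9 FPKM in the others. The ferritin gene Ftl1 was at 17140 FPKM in the untreated library labelled deleted and at 8009 ± 855 FPKM in wild type (SD, n = 2).

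Fos and Dusp1 were higher in the libraries labelled deleted. An exchange of 1 of the pair with a wild-type library is argued against by Ddx3y, which was at least 13.74 FPKM in both and under 1 FPKM in each of the 8 wild-type BCR/ABL libraries; a wrong genotype label on both is not excluded. Immediate early genes without Fos had medians of 0.548 in the untreated and 0.219 in the imatinib pair, at percentile 99.99 or above in both. By the size rule, 7 of 25 members with Fos were higher and 1 lower in the untreated pair, and 3 were higher in the imatinib pair. The rise of Fos may be part of a wider shift of these genes, though most members did not meet the rule. Reads from parts of the alleles that a deletion leaves may also contribute. A gene-level Fos value (15.94 FPKM in the lower library) cannot decide that, and the labels' protocols describe conditional Fos alleles with an inducible recombinase without mentioning a step that activates it.

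The broad difference between the libraries labelled deleted and wild type has at least 2 candidate explanations beside the labelled deletion. Donors of different sex as the whole cause were tested by chromosome, and at most 4.8% of the genes lay on X or Y in either pair, against 3.11% of all genes tested. The planned bound of 50% cannot decide this. It would have needed 86.4% of the tested X and Y genes to differ in the untreated pair and 50.1% in the imatinib pair. Sex can also act on genes of other chromosomes, so this stays open. Another mix of cell types is in line with the markers. Of 8 cell type lists 6 lay beyond the preset outer percentiles of random lists in the same direction in both pairs, 5 lower (stem and progenitor, neutrophil, mast cell and basophil, erythroid and megakaryocyte) and 1 higher (monocyte and macrophage). The label, the mix of cells and the donors coincide in these 2 libraries. The shape of their low values, which sets both and the first untreated library apart from both imatinib libraries and the second untreated library, may mark another run and coincides with the label in the imatinib pair. Effects of each on single genes were not tested. Nor were donor differences other than sex, such as genetic background.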
